A study of Homo sapiens with 6 samples.

How the data were processed

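6 libraries were measured, 3 of T cells from IPF lung explants and 3 of T cells from normal donor blood, grouped by the sample titles and tissue labels. Per the labels' protocols, the lungs were mechanically dissociated, the cell suspensions were stored and thawed, and T cells were stained with anti-CD3 antibodies and sorted on a flow cytometer, while blood CD4+ cells were sorted magnetically. Total RNA, at least 200 ng per the labels, was sequenced on a HiSeq 2000, and the column names carry the same lane for all libraries. Per the labels' protocols, the authors aligned reads to hg38 with CLC Genomics Workbench 8.5.1, which also made the RPKM values (reads scaled by gene length and mapped reads). The gene annotation, strand setting and library kit are not stated. Per the file headers and labels, the authors' deposited p-values and signed fold changes come from that program's empirical analysis of digital gene expression. A positive signed fold change means higher in IPF, as checked on the RPKM values. RPKM values are normalized for length and mapped reads by the authors, not for composition, so a few abundant genes can lower all others.

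The deposited table held 60448 features. Features on the Y chromosome and X-inactivation genes (441) were removed before any step, and 60007 were kept, of which 36758 matched a GENCODE 44 symbol or a RefSeq symbol or synonym. Coordinates are those of GENCODE 44 on GRCh38, the same assembly as hg38. Low RPKM values fell on steps of 1 read, which gave the mapped reads of each library, 11775900 to 18362471. Of 2817 features at a single step, 43.9% matched 1 read over the GENCODE exon length. All 11254 tested genes gave whole reads within 0.05 reads, 1970 of them at the annotated length and 9284 at another length. Since the length was fitted for the latter, these reads served only the comparison of libraries within a group and an added alternative. By these reads, pairs of libraries of a group differed by more than sampling noise, with a median chi-square over noise of 3.05 to 12.5 between blood and 22.6 to 100.5 between lung libraries over genes with at least 50 reads, and no pair looked like a duplicate.

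Genes with at least 1 RPKM in at least 3 of the 6 libraries were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, group as the only term, two-sided, Benjamini-Hochberg adjustment over 11254 genes, threshold 0.05). Unless stated otherwise, fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. Because RPKM are not counts, no count model was used. Gene lists, 43 in all, were fixed before the data were examined, as were the tests, the other settings and the rule for named genes. The 35 lists with at least 3 tested members were compared with all other tested genes by camera with a preset inter-gene correlation of 0.01, and Benjamini-Hochberg adjustment over the lists. At an adjusted p under 0.05, 20 lists were called, and 1, the chemokine ligands, with an estimated correlation. Counts adjusted over the list alone apply the adjustment to the members of a list only. Several lists share members, and macrophages also express many genes of the MHC class II, chemokine, NF-kB, heat shock and immediate early lists.

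Named genes were 18 T cell genes fixed beforehand, the 10 largest increases and 10 largest decreases among called genes whose groups do not overlap and whose mean log2 value is at least 2, and up to 4 tested members with the smallest p of each list. Uncharacterized loci, antisense and small non-coding families, antigen receptor segments, immunoglobulin constant genes, and genes that vary with genotype were not named by the fold rule. The tests were run on simulated data with the observed spread of 11254 genes for this comparison, in which 200 genes were changed. Of those changed 2-fold, 4-fold and 8-fold, 22.4%, 76.1% and 78.8% were recovered, with 6 false calls. Camera called 3.5% of 200 unchanged random lists and 100% of 50 lists raised 2-fold at an unadjusted p under 0.05. Genes were simulated independently of each other and with the same spread in both groups. The real lists had estimated correlations as high as 0.975 (pan T cell) and 0.652 (macrophage and monocyte). These simulations therefore do not give the error rate of the gene or list tests on the real data.

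Other settings fixed beforehand were other pseudocounts, filters, normalizations, variance models, array weights, a replicate block, leaving out each library, other thresholds, an estimated correlation and the rotation test fry. A count test fixed beforehand was not run because the values are RPKM. Added after the data were examined were the omission of IPF lung library 1 together with normal blood library 3, scaling to the geometric mean of the 15 tested pan T cell genes with and without IPF lung library 1, and limma-voom on the recovered reads. Values of near-identical genes (HLA genes, HSPA1A and HSPA1B, CCL3 and CCL4 copies, XCL1 and XCL2, HBA1 and HBA2, small nuclear RNA and histone genes) are uncertain, since it is not known how the authors' counting split shared reads. Overlapping genes are uncertain too. Of the named genes, more than 35% of the GENCODE exon bases overlap another gene in ACTA2, APOC1, CCR6, CD27, CXCR5, DDIT3, ENTPD1, GIMAP5, GZMK, HSPA1B, IGLL5, LAT, NUSAP1, TRDC, TRGC1 and TYMS. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.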

Results

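T cells from the explanted lungs of people with idiopathic pulmonary fibrosis (IPF), a progressive scarring disease of the lung, were compared by RNA sequencing with T cells from the peripheral blood of normal donors. Each group held 3 libraries. The lung cells came from mechanically dissociated, banked and thawed tissue and were flow sorted with an anti-CD3 antibody, and the blood cells were sorted magnetically as CD4+ cells per the labels' protocol, although the sample titles carry CD3. Tissue, disease, sort and handling therefore changed together between the groups, and the non-coding RNA classes reported below leave open that RNA extraction or library preparation did too. The deposited table listed reads scaled by gene length and mapped reads (RPKM) for 6 libraries. The depth read back from the steps of its low values was 12754035, 13877321 and 15282223 mapped reads for normal blood libraries 1 to 3, and 18362471, 16785082 and 11775900 for IPF lung libraries 1 to 3. At that depth a single read over 1 kilobase was worth 0.0545 to 0.0849 RPKM. The labels do not say whether the libraries of a group came from separate donors, so p-values measure the spread between these libraries, which may be technical.

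To identify genes that differed between lung and blood T cells, log2(RPKM + 1) values of the 11254 expressed genes were compared with limma. Of the called genes that the naming rule admits (abundant, without overlap between the groups and outside several non-coding and receptor families), the 10 with the largest increase in IPF lung were C1QB, JUN, C1QA, C1QC, APOC1, CCL18, MARCO, FOSB, APOE and FABP4. The 10 with the largest decrease were 5 mitochondrial tRNA genes, CCR7, GIMAP5, LEF1, RCAN3 and TMEM204. At an adjusted p under 0.05, 1139 genes differed, of which 430 were higher and 709 lower in IPF lung. Of these, 411 higher and 508 lower genes changed at least 2-fold. The values of the groups did not overlap for 5359 genes (47.6% of those tested, against 10% by chance). The median log2 fold change over all tested genes was -0.26. Median-of-ratios scaling moved it to 0.01 and gave 275 higher and 253 lower genes. TPM scaling (the same sum in every library) moved it to -0.53 and gave 373 higher and 376 lower genes.

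IPF lung library 1 stood apart from the other 5 libraries. It held the highest value of 294 of the higher genes (68.4%) and the lowest value of 617 of the lower genes (87%). Without it, 1764 genes differed (637 higher and 1127 lower), and 410 of the 430 higher and 680 of the 709 lower genes were still called. Leaving out IPF lung library 2 or 3 gave 253 and 2956 genes, and leaving out normal blood library 1, 2 or 3 gave 65, 62 and 241. Of 75 named genes followed through these fits, 43, 44 and 33 lost their call without normal blood library 1, 2 or 3, 31 without IPF lung library 2, 1 without IPF lung library 1 and 0 without IPF lung library 3.

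T cell identity genes were present in every library but varied widely within the lung group. CD3E, a chain of the T cell receptor complex (chromosome 11, positions 118304730 to 118316175 of GRCh38), measured 8.88, 89.5 and 142 RPKM in IPF lung libraries 1, 2 and 3 and 152, 154 and 136 RPKM in the blood libraries. TRAC, the receptor alpha constant gene, measured 4.87, 90.4 and 127 RPKM in the lung libraries and 183 ± 24.2 RPKM in blood (SD, n = 3). None of the 15 tested pan T cell genes passed the threshold over all genes or adjusted over the list alone, and their median log2 fold change was -1.42, or -0.31 without IPF lung library 1, when 1 was called lower. The list itself was not called (camera adjusted p = 0.139), although it was called lower when IPF lung library 2 was left out (camera adjusted p = 0.0368). CD4 measured 59.8, 37.9 and 54.9 RPKM in IPF lung libraries 1, 2 and 3 and 67.2 ± 4.76 RPKM in blood (log2 fold change -0.42 ± 0.25 SE, limma adjusted p = 0.25). It was not low in lung library 1 as CD3E was. Relative to the geometric mean of the pan T cell genes, a ratio chosen after the values were seen, CD4 stood at 1535% there against 88% and 93% in lung libraries 2 and 3. Macrophages also express CD4. None of the 4 CD4 lineage genes passed with all libraries and 1 was called lower without IPF lung library 1 (camera adjusted p = 0.629 with all libraries). CD8A, the CD8 co-receptor alpha chain, measured 6.38, 37.4 and 89.8 RPKM in the lung libraries and 9.77, 0.198 and 0.252 RPKM in the blood libraries (log2 fold change 3.55 ± 1.16 SE, limma adjusted p = 0.0879). CD8B did not pass either (log2 fold change 2.33 ± 1.17 SE, limma adjusted p = 0.192). Of the 4 CD8 lineage genes, 2 passed adjusted over the list alone and 2 over all genes without IPF lung library 1, and together they stood above other genes as a list (camera adjusted p = 0.0131), a call that was lost with an estimated correlation (adjusted p = 0.463) and without IPF lung library 3 (camera adjusted p = 0.0749). CD8A passed without IPF lung library 1 (log2 fold change 4.55, limma adjusted p = 0.0401). Blood libraries 2 and 3 held little CD8A, as a CD4+ sort would give. Such a sort of the blood alone would place CD8 genes higher in lung. The rise of this list therefore cannot be attributed to tissue or disease.

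**Figure D1:**
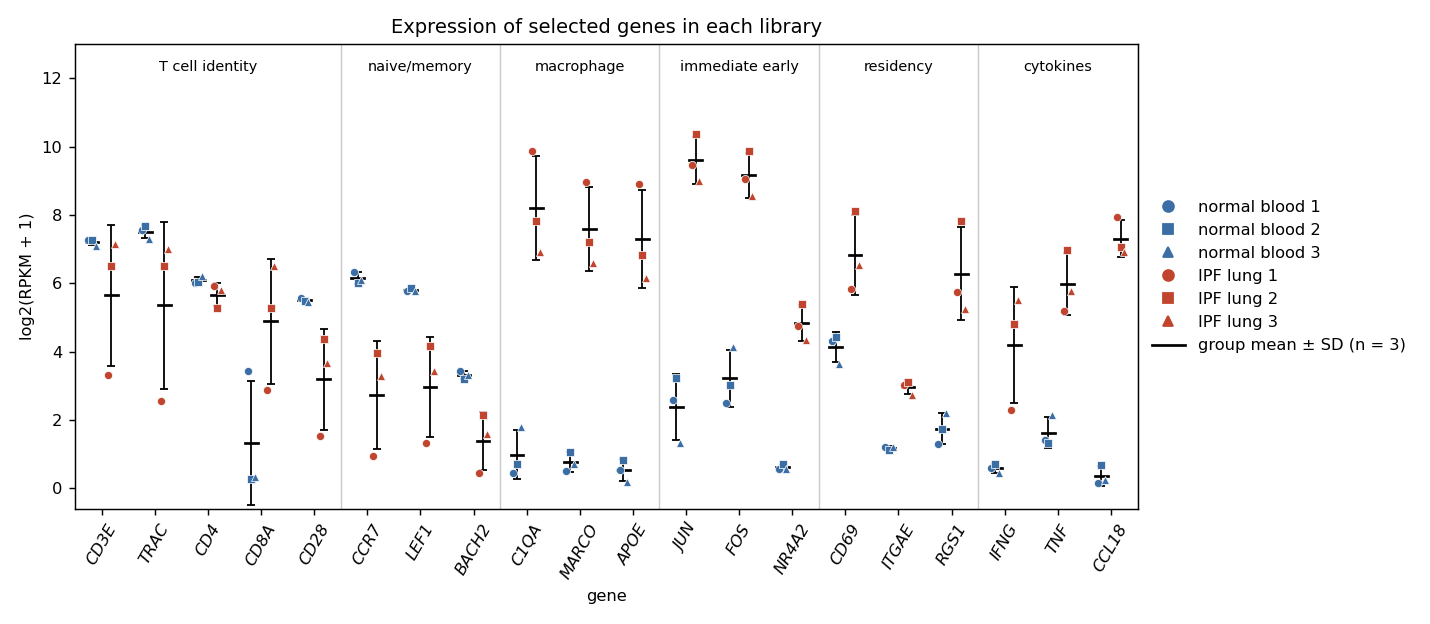
Each point is log2(RPKM + 1) of a gene in a library, with normal blood in blue and IPF lung in red, and black bars give the group mean and SD (n = 3). CD3E was lowest in IPF lung library 1 at 8.88 RPKM, where C1QA was highest at 939 RPKM, and JUN, FOS and NR4A2 lay above blood in all 3 lung libraries.

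Macrophage and monocyte genes were higher in IPF lung. Of 19 tested members, 14 rose (16 adjusted over the list alone) and 0 fell, with a median log2 fold change of 5.49 (camera adjusted p = 2.01e-18, adjusted p = 0.309 with an estimated correlation). C1QB, a chain of complement C1q (chromosome 1, positions 22652762 to 22661637), measured 301 ± 253 RPKM in lung and 0.439 ± 0.222 RPKM in blood (SD, n = 3; log2 fold change 7.38 ± 0.58 SE, limma adjusted p = 0.00318). MARCO, a scavenger receptor of alveolar macrophages, measured 246 ± 217 RPKM in lung and 0.718 ± 0.355 RPKM in blood (log2 fold change 6.83 ± 0.59 SE, limma adjusted p = 0.00374). APOE and FABP4, both lipid carriers, rose by 6.77 and 6.52 on the log2 scale (limma adjusted p = 0.00607 and 0.0119). C1QA measured 939, 226 and 118 RPKM in IPF lung libraries 1, 2 and 3, so the library with the lowest CD3E had the highest C1QA. The lung libraries therefore cannot be read as T cell RNA alone. Without IPF lung library 1, 13 members were called, with a median log2 fold change of 4.58. Normal blood library 3 also stood above the other blood libraries in the mean log2(RPKM + 1) of this list, at 2.45 against 0.91 and 1.01. With IPF lung library 1 and normal blood library 3 both left out, 18 members were called higher.

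Genes of naive and central memory T cells stood lower in IPF lung as a list. Of 16 tested members, 5 fell (12 adjusted over the list alone) and none rose, and the median log2 fold change was -1.90 (camera adjusted p = 0.000302, adjusted p = 0.463 with an estimated correlation). CCR7, the chemokine receptor that guides T cells into lymph nodes (chromosome 17, positions 40553769 to 40565472), measured 8.12 ± 6.89 RPKM in lung and 70.4 ± 8.45 RPKM in blood (SD, n = 3; log2 fold change -3.42 ± 0.73 SE, limma adjusted p = 0.0384). LEF1, a transcription factor of naive T cells, measured 9.37 ± 7.65 RPKM in lung and 54.8 ± 2.32 RPKM in blood (log2 fold change -2.83 ± 0.67 SE, limma adjusted p = 0.0476). BACH2, SATB1 and LRRN3 fell by 1.92, 1.84 and 1.54 on the log2 scale. The pan T cell genes were low in IPF lung library 1, where CCR7 measured 0.934 RPKM. In the other lung libraries CCR7 measured 14.7 and 8.74 RPKM, and without IPF lung library 1 the list held 11 called members and a median of -1.41. The adjusted p ranged from 0.00577 to 0.142 for CCR7 and 0.00981 to 0.159 for LEF1 over the fits that left out a library, and for both exceeded 0.05 without IPF lung library 2 or any single blood library.

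Immediate early genes, which are transcribed within minutes of a stimulus, rose in IPF lung. Of 19 tested members, 17 rose and 1 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 3.14 (camera adjusted p = 9.83e-18, adjusted p = 0.282 with an estimated correlation). JUN, a subunit of AP-1 (chromosome 1, positions 58776845 to 58784048), measured 839 ± 416 RPKM in lung and 4.96 ± 3.43 RPKM in blood (SD, n = 3; log2 fold change 7.22 ± 0.56 SE, limma adjusted p = 0.00309). FOS measured 614 ± 288 RPKM in lung and 9.42 ± 6.2 RPKM in blood (log2 fold change 5.94 ± 0.51 SE, limma adjusted p = 0.00374), and the nuclear receptor gene NR4A2 measured 28.9 ± 11.2 RPKM in lung and 0.542 ± 0.0816 RPKM in blood (log2 fold change 4.21 ± 0.28 SE, limma adjusted p = 0.00197). The member that fell was MYC, a regulator of cell growth, which was named after its values were seen (log2 fold change -1.26 ± 0.27 SE, limma adjusted p = 0.038). Without IPF lung library 1 the list held 16 higher and 1 lower members. The macrophage genes were also higher in all 3 lung libraries, but their mean was highest in IPF lung library 1 (7.84 against 5.82 and 5.78 in libraries 2 and 3), while that of the immediate early genes was highest in IPF lung library 2 (6.40 against 5.68 in library 1 and 5.11 in library 3).

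Some inflammatory mediators rose with them. Of 14 NF-kB target genes, 5 rose (8 adjusted over the list alone) and none fell (camera adjusted p = 2.01e-05, adjusted p = 0.309 with an estimated correlation). They were TNFAIP3 and NFKBIA, feedback inhibitors of NF-kB (log2 fold changes 3.73 and 3.68), the cytokine gene TNF (4.34), the surface gene CD83 (3.90) and the adhesion gene ICAM1 (2.11), the last named after its values were seen. TNF measured 71.2 ± 47.2 RPKM in lung and 2.21 ± 1.07 RPKM in blood (log2 fold change 4.34 ± 0.48 SE, limma adjusted p = 0.00849). Of 13 chemokine ligands, 10 rose (12 adjusted over the list alone) with a median log2 fold change of 4.34 (camera adjusted p = 1.42e-13). This was the only list of 35 tested that was also called with an estimated correlation (adjusted p = 0.0433 with an estimated correlation), and it was not called that way without IPF lung library 1 (adjusted p = 0.158 with an estimated correlation). CCL18, a chemokine made by alveolar macrophages, measured 244, 133 and 119.9 RPKM in the lung libraries and 0.306 ± 0.273 RPKM in blood (log2 fold change 6.94 ± 0.33 SE, limma adjusted p = 0.000704). CCL4, which activated T cells, NK cells and macrophages secrete, measured 77 ± 32.6 RPKM in lung and 2.01 ± 1.38 RPKM in blood (log2 fold change 4.72 ± 0.49 SE, limma adjusted p = 0.00686). IFNG, which encodes interferon gamma (chromosome 12, positions 68154768 to 68159740), measured 25 ± 20.2 RPKM in lung and 0.514 ± 0.137 RPKM in blood (log2 fold change 3.60 ± 0.77 SE, limma adjusted p = 0.0381), and with TNF it made up the called members of the 7 tested Th1 genes (camera adjusted p = 0.0221, adjusted p = 0.632 with an estimated correlation). Of the Th1 genes, 3 rose without IPF lung library 1. The Th1 list was not called without IPF lung library 2 or 3 (camera adjusted p = 0.0719 and 0.148), and its median was -0.22 without library 3.

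Genes associated with tissue residency differed between the groups in numbers that depended on IPF lung library 1. Of 11 tested genes known to be higher in resident T cells, 3 rose (8 adjusted over the list alone) and none fell (camera adjusted p = 3.91e-08, adjusted p = 0.282 with an estimated correlation). Without IPF lung library 1, 9 rose and 0 fell (camera adjusted p = 1.05e-10, adjusted p = 0.235 with an estimated correlation). The 3 called with all libraries were RGS1, a regulator of G protein signalling (4.53 on the log2 scale), CD69, an activation and retention marker (2.69), and ITGAE, which encodes the integrin CD103 (1.78). ITGAE measured 6.84 ± 1.05 RPKM in lung and 1.27 ± 0.0874 RPKM in blood (SD, n = 3; log2 fold change 1.78 ± 0.17 SE, limma adjusted p = 0.00552) and 7.14, 7.71 and 5.66 RPKM in IPF lung libraries 1, 2 and 3. The pan T cell genes were lowest in IPF lung library 1, where ITGAE was not, and relative to their geometric mean ITGAE stood at 183% in that library against 17.9% and 9.6% in lung libraries 2 and 3. CXCL13, a B cell attractant that some lung and tumour T cells secrete, measured 1.22, 17.3 and 13.1 RPKM in the lung libraries and at most 0.0504 RPKM in blood, and passed without IPF lung library 1 (3.98, limma adjusted p = 0.00052) but not with it (log2 fold change 3.03 ± 0.75 SE, limma adjusted p = 0.0511). Over the fits that left out a library, the adjusted p ranged from 0.00504 to 0.0553 for ITGAE, 0.0176 to 0.141 for CD69, 0.0165 to 0.0877 for RGS1, 0.000743 to 0.141 for IFNG and 0.00422 to 0.0553 for TNF. It exceeded 0.05 for each of them without normal blood library 1 or 2, and for CD69 and IFNG also without normal blood library 3 or IPF lung library 2. CXCR6 was listed below 1 RPKM in every library and was not tested. Of 11 genes known to be lower in resident cells, 1, CCR7, fell (5 adjusted over the list alone, and 4 without IPF lung library 1). S1PR5 and ITGB2, named after their values were seen, had positive log2 fold changes that did not pass (1.45 and 0.57). This list was not called (camera adjusted p = 0.139), although of the fits that left out a library it was called lower without IPF lung library 3 (camera adjusted p = 0.0426).

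Few receptor genes that tune T cell activation were called with all libraries. CD28, the main co-stimulatory receptor (chromosome 2, positions 203706475 to 203738912), measured 11.1 ± 8.93 RPKM in lung and 44.4 ± 1.45 RPKM in blood (SD, n = 3) and did not pass (log2 fold change -2.32 ± 0.68 SE, limma adjusted p = 0.0713). Without IPF lung library 1 it was called lower (log2 fold change -1.49, limma adjusted p = 0.0176). None of the 11 tested genes of the co-stimulatory receptor list passed (camera adjusted p = 0.593), and without IPF lung library 1 1 rose and 2 fell. Of 14 tested genes of the co-inhibitory receptor list, HAVCR2, which encodes TIM-3 and is also expressed by macrophages, rose (log2 fold change 2.60 ± 0.57 SE, limma adjusted p = 0.0389). It measured 35.9, 12.7 and 8.62 RPKM in IPF lung libraries 1, 2 and 3. Without IPF lung library 1, 5 members rose, HAVCR2, PDCD1, LAG3, TOX and BATF. The list is not of receptors alone, and TOX and BATF encode transcription factors. LAG3, TOX and BATF were named after their values were seen. The list median moved from 0.34 to 0.99 (camera adjusted p = 3.43e-05, adjusted p = 0.235 with an estimated correlation). The list as a whole was called higher (camera adjusted p = 0.0202, adjusted p = 0.463 with an estimated correlation), but not without IPF lung library 2 or 3 (camera adjusted p = 0.17 and 0.0738). CTLA4 measured 2.49, 48.4 and 13.3 RPKM in the lung libraries and 9.41 ± 1.22 RPKM in blood, a difference within the spread (log2 fold change 0.38 ± 0.87 SE, limma adjusted p = 0.76). PDCD1, which encodes PD-1, did not pass with all libraries (log2 fold change 0.97 ± 0.62 SE, limma adjusted p = 0.279) and passed without IPF lung library 1 (1.73, limma adjusted p = 0.00922). Of 21 cytotoxic effector genes, IFNG alone passed, none passed adjusted over the list alone, 2 passed without IPF lung library 1, and the list was called higher (camera adjusted p = 0.000164, adjusted p = 0.632 with an estimated correlation). GZMB, GZMK and PRF1 did not pass (limma adjusted p = 0.157, 0.596 and 0.692). GNLY, a granule protein of killer cells, measured 8.07, 29.7 and 380.2 RPKM in the lung libraries. KLRF1, an NK cell receptor, measured 1.12, 3.4 and 48.1 RPKM there. Both were highest in IPF lung library 3. Because only the blood cells were sorted as CD4+, the part of the sort in the cytotoxic list cannot be told apart from tissue or disease.

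Some antigen presentation and stress genes rose in lung. Of 10 MHC class II genes, 4 rose (9 adjusted over the list alone) with a median log2 fold change of 2.67 (camera adjusted p = 7.18e-08, adjusted p = 0.388 with an estimated correlation). HLA-DRB1 measured 1534, 566 and 251 RPKM in IPF lung libraries 1, 2 and 3 and 30.8, 33.4 and 133 RPKM in blood, where library 3, high in macrophage and monocyte genes, was highest (log2 fold change 3.52 ± 0.80 SE, limma adjusted p = 0.0427). HSPA5, a chaperone of the endoplasmic reticulum, was the called member of 13 heat shock genes (log2 fold change 2.15 ± 0.37 SE, limma adjusted p = 0.0254), with 4 called adjusted over the list alone (camera adjusted p = 2.21e-06, adjusted p = 0.463 with an estimated correlation). The mean log2(RPKM + 1) of the heat shock list was 7.33, 7.30 and 5.01 in IPF lung libraries 1, 2 and 3 and 4.57, 4.63 and 4.94 in the blood libraries, so lung library 3 lay near blood library 3. HSPA1B measured 989.5, 1685 and 28.4 RPKM in the lung libraries against 5.65 ± 3 RPKM in blood and did not pass (log2 fold change 5.91 ± 1.47 SE, limma adjusted p = 0.0511), and its reads may be shared with its near-identical neighbour HSPA1A. HSPA5 and DDIT3 were the called members of 14 unfolded protein response genes (7 higher and 1 lower adjusted over the list alone, 4 higher without IPF lung library 1, camera adjusted p = 7.46e-06, adjusted p = 0.308 with an estimated correlation). Of 18 glycolysis genes, SLC2A3, PFKFB3 and LDHA rose (7 higher and 1 lower adjusted over the list alone, 3 and 1 without IPF lung library 1, camera adjusted p = 6.14e-06, adjusted p = 0.382 with an estimated correlation). Of 15 cell cycle genes, NUSAP1, TK1 and TYMS rose by 0.94, 0.98 and 0.78 on the log2 scale (5 adjusted over the list alone, camera adjusted p = 3.38e-05, adjusted p = 0.356 with an estimated correlation). NUSAP1 measured 4.46 ± 0.412 RPKM in lung. Exons of NUSAP1 and TYMS overlap those of neighbouring genes over 86.8% and 47.9% of their length. None of the 36 cytosolic ribosomal protein genes passed, and they stood below other genes as a list (median -0.71, or -0.43 without IPF lung library 1, camera adjusted p = 0.000326 with all libraries, adjusted p = 0.763 with an estimated correlation). That median was 0.85 when each library was scaled to its pan T cell genes, a scaling added after the data were seen that moved the median of all genes to 1.05.

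Among the remaining lists of T cell states, CTSH, a lysosomal protease, was the called member of 6 Th17 genes, and OASL, an antiviral enzyme-like gene, of 18 type I interferon genes (log2 fold changes 2.86 and 2.43), each also called adjusted over the list alone. CTSH (55.8, 13.9 and 13.1 RPKM in IPF lung libraries 1, 2 and 3) and OASL (27.2, 8.64 and 5.94 RPKM) were highest in library 1, as the macrophage genes were. Neither list was called (camera adjusted p = 0.848 and 0.435), although of the fits that left out a library the interferon list was called without normal blood library 3 (camera adjusted p = 0.0423). SMAD7 and TGFBI rose among 12 TGF-beta response genes (5 adjusted over the list alone, 3 without IPF lung library 1, camera adjusted p = 0.0308, adjusted p = 0.309 with an estimated correlation), a list not called without IPF lung library 3 (camera adjusted p = 0.123). TGFBI, a matrix protein that macrophages also make, measured 101, 26.9 and 19.8 RPKM in IPF lung libraries 1, 2 and 3. VEGFA and DDIT4 rose and PDK1 and BNIP3 fell among 8 hypoxia genes (4 higher and 2 lower adjusted over the list alone, 3 and 2 without IPF lung library 1), which were not called as a list (camera adjusted p = 0.226). No member of the regulatory T cell, Th2, gamma-delta T cell or MAIT cell lists passed, over all genes or adjusted over its list alone (camera adjusted p = 0.608, 0.563, 0.59 and 0.848), and 1 regulatory T cell gene passed without IPF lung library 1. FOXP3, the regulatory T cell transcription factor, measured 0.988, 20.6 and 4.84 RPKM in the lung libraries (log2 fold change -0.14 ± 0.79 SE, limma adjusted p = 0.903). No T follicular helper gene passed over all genes, CXCL13 passed adjusted over the list alone, and of the fits that left out a library the list was called only without IPF lung library 1 (camera adjusted p = 0.139 with all libraries and 0.000503 without it, when 2 members rose). That call was lost with an estimated correlation (adjusted p = 0.235). None of 23 nuclear respiratory chain genes passed, with a list median of 0.32 (camera adjusted p = 0.00138, adjusted p = 0.632 with an estimated correlation). That median was 0.17 without IPF lung library 1 (camera adjusted p = 0.0306). The mean log2(RPKM + 1) was 4.79 in IPF lung library 1, 4.28 in libraries 2 and 3, and 4.25 in normal blood library 3.

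Markers of other cell types were examined in the same way. Of 5 NK cell genes, XCL2 rose (2 adjusted over the list alone, 2 without IPF lung library 1, camera adjusted p = 0.00651, adjusted p = 0.309 with an estimated correlation). The members TYROBP (370, 109 and 60.7 RPKM in IPF lung libraries 1, 2 and 3) and FCER1G (408, 82 and 69.8 RPKM) were highest in library 1, as the macrophage genes were. XCL2 and KLRF1 were instead highest in IPF lung library 3 (18.9 and 48.1 RPKM). No neutrophil gene passed over all genes and 4 of 5 did adjusted over the list alone (camera adjusted p = 0.000693, adjusted p = 0.416 with an estimated correlation). The mean log2(RPKM + 1) of this list was 0.56, 0.61 and 3.84 in normal blood libraries 1, 2 and 3. Library 3 also stood above the other blood libraries in macrophage and monocyte genes. With IPF lung library 1 and normal blood library 3 both left out, 5 neutrophil genes were called higher. Among 5 dendritic cell genes, the chemokine gene CCL17 rose and the IgE receptor gene FCER1A fell (1 higher and 2 lower adjusted over the list alone, 1 and 0 without IPF lung library 1, camera adjusted p = 0.928). No B cell or plasma cell gene passed (camera adjusted p = 0.848 and 0.848). A fit without IPF lung library 1 called 1 B cell gene and 1 alveolar type 2 epithelium gene higher. Lists with fewer than 3 tested members had no list test. FN1, which encodes fibronectin and is also made by macrophages, rose among the fibroblast genes (log2 fold change 6.34 ± 0.61 SE, limma adjusted p = 0.00507). It measured 358, 96 and 64.5 RPKM in IPF lung libraries 1, 2 and 3. ACTA2 did not pass. PPBP rose among the 2 tested platelet genes (log2 fold change 4.25 ± 0.69 SE, limma adjusted p = 0.0221). The other, GP1BA, did not pass, and its signed fold change in the authors' deposited table was -1.56. With all libraries, no tested member passed among the alveolar type 2 epithelium, airway epithelium, ciliated epithelium and erythroid genes, of which the last 3 lists held 1 tested gene each, SCGB1A1, CAPS and HBA2 (limma adjusted p over all genes = 0.0954, 0.279 and 0.055). No mast cell or endothelium gene was expressed widely enough to be tested. SCGB1A1, a secretory protein of airway club cells, measured 3.18, 2.76 and 100.4 RPKM in the lung libraries and was listed at 0 in every blood library.

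**Figure D2:**
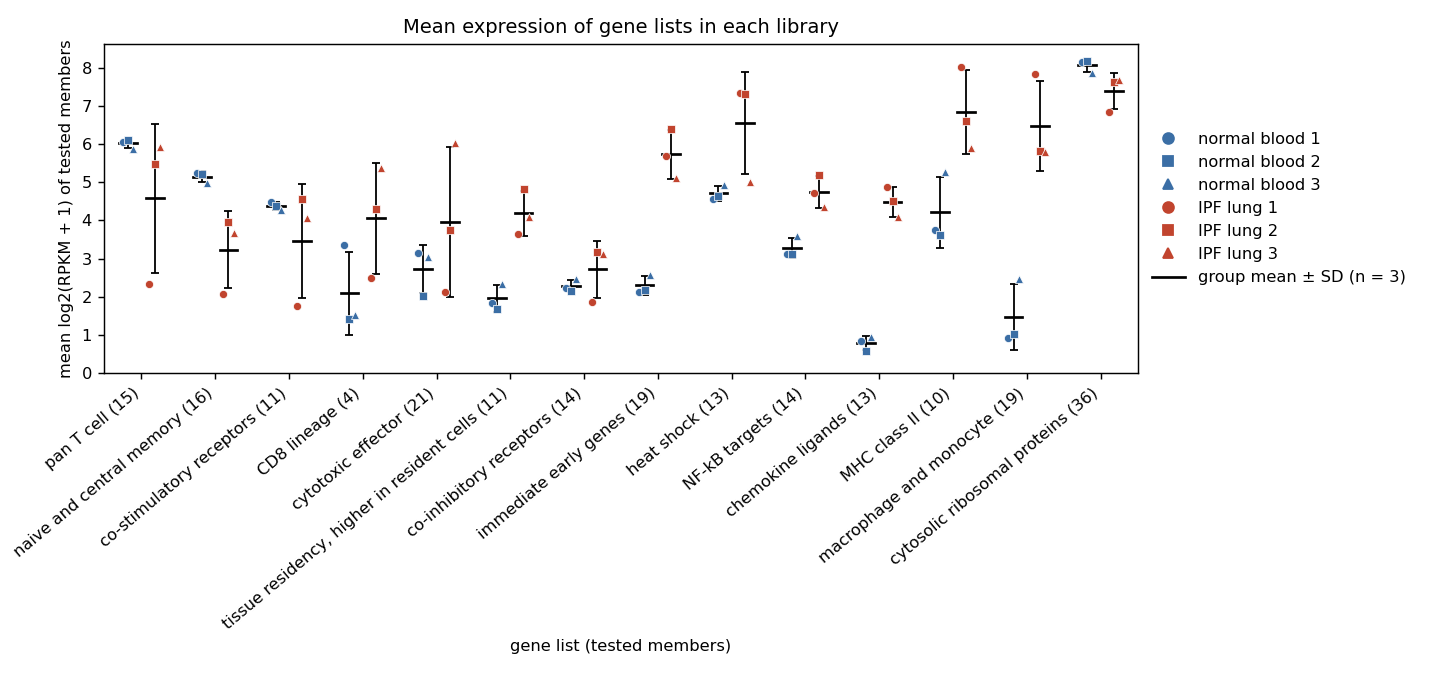
Each point is the mean log2(RPKM + 1) over the tested members of a gene list in a library, with normal blood in blue and IPF lung in red, and black bars give the group mean and SD (n = 3). The pan T cell mean was 2.34 in IPF lung library 1 and 5.47 and 5.91 in libraries 2 and 3, and the macrophage and monocyte mean was 7.84, 5.82 and 5.78 in the same libraries.

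Non-coding RNA classes separated the groups as well. Mitochondrial tRNA genes made up 5 of the 10 named genes with the largest decrease. MT-TP, the tRNA gene for proline (mitochondrial chromosome, positions 15956 to 16023), measured 0.267 ± 0.462 RPKM in lung and 46.8 ± 15 RPKM in blood (SD, n = 3; log2 fold change -5.25 ± 0.33 SE, limma adjusted p = 0.0017), and MT-TG was listed at 0 in every lung library against 33.4 ± 7.91 RPKM in blood. The other classes were chosen after their values were seen. The 22 mitochondrial tRNA genes summed to 2.74 ± 0.331 RPKM in lung and 186 ± 27.2 RPKM in blood (SD, n = 3). Small nuclear RNA features moved the other way and summed to 345 ± 172 RPKM in lung and 56.1 ± 5.03 RPKM in blood, and replication-dependent histone genes to 103 ± 65.2 RPKM in lung and 25.5 ± 5.57 RPKM in blood. Of 28 small nuclear RNA features with a mean of at least 0.5 RPKM, 21 were higher in every lung library than in any blood library and 1 was lower. The mean was taken over all 6 libraries, so features at 0 in blood entered through their lung values, which favours the higher count. Among all tested genes the groups did not overlap, in either direction, for 47.6%. The 2 mitochondrial rRNA genes summed to 6293 ± 2749.7 RPKM in lung and 3164 ± 128 RPKM in blood, and the 13 mitochondrial mRNA genes to 52611 ± 6577 RPKM in lung and 42053 ± 2801 RPKM in blood. With 3 libraries against 3, an exact two-sided permutation test of such a sum cannot give a p below 0.1. Many small nuclear RNA and histone genes have near-identical copies, so their single values are uncertain.

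**Figure D3:**
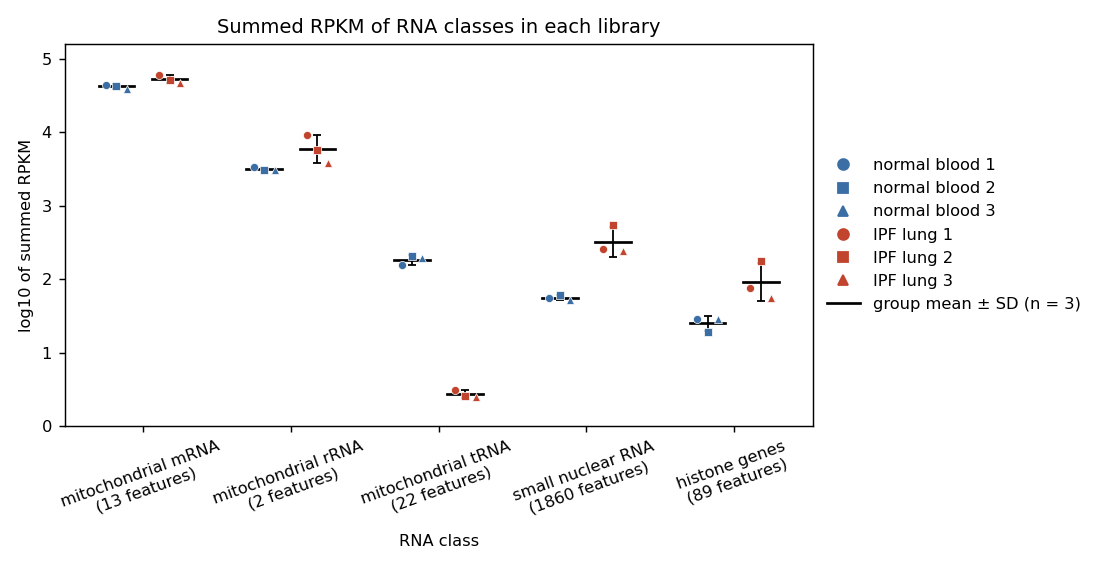
Each point is the log10 of the RPKM summed over all features of an RNA class in a library, with normal blood in blue and IPF lung in red, and black bars give the mean and SD of the log10 values (n = 3). Mitochondrial tRNA sums lay between 2.52 and 3.12 RPKM in lung and between 155 and 206 RPKM in blood.

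The authors' deposited table holds its own comparison of the groups. It gave a p under 0.05 for 1852 of the features kept here, and 484 after Benjamini-Hochberg adjustment made here, of which 429 were higher and 55 lower in IPF. The adjusted calls of the authors' deposited table shared 334 genes with the limma calls, all 334 in the same direction, while 805 genes were called by limma only. In the authors' deposited table JUN was 204-fold and CCL18 483-fold higher in IPF. CCR7 and CD28 were lower there, with signed fold changes of -7.21 and -3.34 (unadjusted p = 2.12e-08 and 0.000676 in the authors' deposited table).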

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

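The settings in this part were planned except for those said to be added. Against 1139, 430 and 709 genes differing, higher and lower, the counts were 700, 380 and 320 with a pseudocount of 0.1 and 1002, 432 and 570 with 0.5. They were 154, 91 and 63 with no filter on low values, where 27478 genes were tested, and 431, 231 and 200 with a minimum of 5 RPKM. Quantile normalization gave 1302, 545 and 757, median-of-ratios scaling 528, 275 and 253 and TPM scaling 749, 373 and 376. Without the variance trend the counts were 1048, 409 and 639, with robust eBayes 1066, 400 and 666 and with array weights, whose estimation did not converge, 8143, 2331 and 5812. Requiring a 2-fold change gave 919, 411 and 508, and an adjusted p under 0.01 gave 89, 58 and 31. Over the 6 fits that left out a library the counts ranged from 62 to 2956 differing, 41 to 741 higher and 21 to 2215 lower. Of the added settings, omitting IPF lung library 1 and normal blood library 3 gave 1842, 951 and 891, pan T cell scaling 10, 10 and 0 (limma, with 878 higher and 73 lower at an unadjusted p under 0.05), the same without IPF lung library 1 808, 553 and 255 and voom on recovered reads 324, 151 and 173. Except for fewer tested genes or libraries, the cause was not tested. With all libraries 20 lists were called, with the leave-out fits 17 to 21, with an estimated correlation 1 and with fry 5. The planned count test was not run because the file holds RPKM.

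The replicate block gave 44, 34 and 10 genes. Libraries of the same number did not deviate together (correlations -0.39, 0.26 and -0.32), and not every library correlated best with its own number. The numbers were not taken to pair the samples, since lung and blood came from patients and normal donors. With 3 libraries in each group, these correlations cannot exclude a batch shared by number.

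Among named genes, FOXP3 reversed to 1.66 with array weights (adjusted p = 0.000944, range over its alternatives 0.000944 to 0.987). The weights of IPF lung libraries 1, 2 and 3 were 0.0822, 18.7 and 0.208. The lung side of that fit therefore rested mostly on library 2, where FOXP3 measured 20.6 RPKM, and so did the gene counts with array weights. The plasma cell list median changed sign under pan T cell scaling, to 0.0747 (camera adjusted p = 0.0347, range 0.0347 to 0.988). That scaling moved the median log2 fold change of all tested genes to 1.05. The list median stayed below it, so its positive sign is not a rise relative to other genes. No other named gene or list reversed while called. APOC1, APOE, C1QB, C1QC, CCL18, FOS, FOSB, JUN and MARCO were called with all libraries and under all 21 alternatives run for named genes. The depth of 11775900 to 18362471 reads limits genes near 1 RPKM most.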

Other observations

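All tests and ratios in this part were chosen after the values were seen. Relative to the geometric mean of 15 pan T cell genes in the same library, several genes lay above every blood library in all 3 lung libraries. CXCL13 stood at 31.2, 40.1 and 22.2% of that mean in IPF lung libraries 1, 2 and 3, while in blood it was above 0 only in library 2, at 0.0737%. IFNG stood at 99.8, 62.5 and 74.8% in lung and 0.786, 0.952 and 0.651% in blood. The co-inhibitory receptor genes PDCD1, CTLA4 and TIGIT stood at 24.5, 23.7 and 11.8%, 63.9, 112 and 22.5%, and 28.9, 53.1 and 37.3% in the lung libraries, against 2.26, 3.14 and 3.43%, 14.6, 15.4 and 14.1%, and 19.4, 15.4 and 10.2% in blood. CCR7 and CD28 lay below every blood library in all 3, with CD28 at 48.3, 45.8 and 19.8% in lung and 70.2, 64.3 and 74.8% in blood. Of the co-stimulatory list, CD40LG also lay below, but TNFRSF18 (40.8, 44.3 and 11.3% in lung) and TNFRSF4 (35.7, 47.9 and 9.37%) lay above every blood library. The rise was thus not confined to co-inhibitory genes. Scaling to the pan T cell genes moved the median log2 fold change of all tested genes to 1.05, so a higher ratio alone does not set a gene apart. The ratio is not specific to T cells in IPF lung library 1, which was rich in macrophage transcripts. There CD4, HAVCR2 and CD69 stood at 1535%, 921% and 1424%, against 88%, 29.4% and 645% in library 2 and 93%, 14.6% and 154% in library 3. For each of these genes an exact two-sided permutation test of 3 against 3 libraries cannot give a p below 0.1.

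Single libraries differed in transcripts that are listed as markers of other cell types. Their source was not tested. The anti-CD3 sort should remove NK and airway cells from the lung libraries, but macrophage transcripts were high after the same sort. IPF lung library 3 had KLRF1 at 81.4% and GNLY at 644% of its pan T cell mean, against 28.8% and 207% in library 1 and 7.9% and 69% in library 2. Cytotoxic T cells express these genes too, and CD8A was also highest in IPF lung library 3, at 89.8 RPKM. SCGB1A1 measured 3.18, 2.76 and 100.4 RPKM, SCGB3A2 0.101, 1.05 and 17.7 RPKM and SFTPB 0.172, 1.52 and 10 RPKM in IPF lung libraries 1, 2 and 3, while LAMP3 was highest in library 2 (0.685, 6.39 and 2.63 RPKM). Normal blood library 3 held more of some transcripts known from monocytes and plasmacytoid dendritic cells than the other blood libraries, with FCN1 at 43.9, CSF1R at 33.5 and LILRA4 at 6.93 RPKM against at most 1.61, 0.578 and 0.133 RPKM. Normal blood library 1 held CD8A at 9.77 RPKM against 0.198 and 0.252 RPKM in the other blood libraries. TIGIT and the genes of this paragraph, apart from KLRF1, GNLY, CD8A, SCGB1A1 and LAMP3, were named after their values were seen.

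Of the 1139 genes that differed, 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split alone (1 of 10) gave as many, and the highest of the others gave 0 (limma), with at most 531 genes at an unadjusted p under 0.05 against 3985 in the real split. Every other split mixes lung and blood libraries in both arms. The difference between lung and blood then adds to the spread within the arms and holds the calls down, so these counts decide nothing.

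Naive and central memory genes stood lower in IPF lung as a list, and the pan T cell genes were low in IPF lung library 1. The log2 values of this paragraph were taken on RPKM + 0.1, not RPKM + 1. A smaller share of T cell RNA would lower both alike, but the median naive gene moved by -1.50 ± 0.35 (SE) on the log2 scale relative to the median pan T cell gene, with -1.36, -1.73 and -2.54 in the lung and -0.31, -0.43 and -0.40 in the blood libraries, so dilution is argued against as the whole cause. Selection of CD4+ cells in blood only could contribute, but whether CD8 T cells carry fewer of these transcripts was not tested. Relative to CD40LG, a gene of CD4 T cells, the median naive gene fell by 0.73 ± 0.31, and because sort and group coincide and CD40LG also responds to activation, this cannot be told apart from a difference of tissue or disease, which was not tested.

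Immediate early genes rose in all 3 lung libraries, where macrophage genes were also high. The log2 values of this paragraph were taken on RPKM + 0.1. They are therefore not on the scale of the median of 3.14 given above for the immediate early genes. The 17 called immediate early genes had a median log2 ratio of IPF lung library 2 to library 1 of 0.82 (quartiles 0.17 and 1.35), and the 14 called macrophage genes -2.07 (quartiles -2.23 and -1.78), but immediate early genes are inducible and no table gives their level per macrophage, so macrophage RNA as their source cannot be told apart from a rise in T cells. The most abundant listed macrophage transcript was LYZ, at 3050.4, 666 and 591 RPKM in lung libraries 1, 2 and 3. Of the 19 tested members, 3 reached 1 RPKM in every blood library. An anti-CD3 sort should remove such cells, but these values show that macrophage transcripts remained in the sorted lung libraries. Dissociation and thawing of the lung cells may also induce the immediate early genes. Their median rise over the blood mean was 4.59, 5.39 and 3.89 in lung libraries 1, 2 and 3, while that of the heat shock genes was 1.77, 2.13 and 0.03, and as no blood library was handled in this way, handling, tissue and disease cannot be told apart.

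Mitochondrial tRNA genes were nearly absent from the lung libraries, and less mitochondrial RNA is argued against, because the 15 mitochondrial mRNA and rRNA genes had a median log2 fold change of 0.39 (quartiles -0.05 and 0.65). A loss of short RNA during library preparation remains a candidate explanation. The 34 other features of at most 200 bases had a median log2 fold change of 1.99 (quartiles 0.29 and 3.12), but all except 7 of them are small nuclear RNA. Those 7 had a median of -0.28 (quartiles -0.57 and -0.21), and the shortest spans 88 bases and the mitochondrial tRNA genes 59 to 75, so the explanation cannot be told apart from a difference of tissue or disease, which was not tested. A difference in RNA extraction or library preparation between the groups, which the labels neither state nor exclude, stays open for the small nuclear RNA and histone rises as well and limits the comparison of the groups as a whole.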
